A study of Mus musculus with 3 samples.

How the data were processed

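Histone H3 trimethylated on lysine 4 (H3K4me3), a mark of promoters, was profiled by chromatin immunoprecipitation and sequencing in granulosa cells of C57BL/6 female mice. Per the labels' protocols, follicles were stimulated with eCG (4 IU) and ovulation was triggered with hCG (5 IU), ovaries were taken before hCG (0 h) and at 4 h and 12 h after it, and follicles were punctured to isolate the cells. Libraries were amplified for 18 PCR cycles and sequenced on a Genome Analyzer GAIIx, per the labels' protocols. There was 1 library per time, so no replicate check of any difference was possible, and how many mice went into each library is not given in the sources used here.

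The authors deposited a peak list per sample, each with the chromosome, start, end and name of every peak in bp positions, and no score, height or read depth. The submitters' processing notes list CASAVA 1.8, Bowtie2 2.2.3, MACS2 2.0.9 and the mm10 build. The peak threshold and the use of an input control are not given in the sources used here. Per the file contents, the peak names of the 0 h and 4 h lists carry the tag nolambda and those of the 12 h list do not, and per the labels the 12 h library ran in lane 5 and the others in lane 4. The name of the 12 h list itself carries the tag, so whether its peak-calling setting differed is unknown. The sequencing depth of each library is unknown. Intervals are 95% Clopper-Pearson intervals and cover counting error alone.

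Peaks on chromosomes 1 to 19, X and Y were used. The build was checked by the share of annotated gene starts with a peak within 1 kb. It was 24.6%, 25.6% and 24.4% at 0 h, 4 h and 12 h, against 3.09%, 3.23% and 3.04% after shifting the genes. A peak was shared with another library when at least 1 bp overlapped. The mouse annotation used here gives the start and end of 21887 protein-coding genes without their strand, so the planned windows around transcription start sites were replaced by windows around gene ends, a choice made after the annotation was seen. For each gene the end with more covered bp within 1 kb, summed over the 3 libraries, was taken as its marked end. Without strand the marked end can be the end opposite the promoter. A promoter call or promoter peak below therefore means a peak at the marked end. A gene was called when a peak lay within 1 kb of the marked end. Breadth was the number of bp covered by peaks within 5 kb of it. Breadth changes are log2 ratios for genes called at both times, minus the median of all such genes. A gene whose promoter lies inside the gene, away from both ends, is missed by this rule. Location classes were within 1 kb of either gene end, elsewhere in a gene, and intergenic.

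The comparisons were 0 h to 4 h, 4 h to 12 h and 0 h to 12 h. Before the data were examined, 18 gene lists were fixed, 9 of genes known to respond in granulosa cells, 7 of other ovarian cell types, a housekeeping list and a list of unrelated lineages. Of their 485 members, 484 were found in the annotation. For each list, members that gained or lost a call and the median centred breadth ratio were set against 10000 random lists of the same size (seed 7). Random lists for gains were drawn from all genes not called at the earlier time, and for losses from all genes called then, without matching. Matching these on promoter GC content, planned if a genome was given, was not done because none was. Those for breadth were matched on the decile of mean covered bp. The percentiles describe these libraries and are no p-values, and 97.5 and 2.5 are used as reading limits. Among 54 percentiles for gains, 12 were at or above 97.5, and among 54 for losses, 6 were. Among 30 percentiles for breadth, 6 were at or above 97.5 and 4 at or below 2.5. No number by chance is given, since the comparisons share libraries and lists with few called members can take few values. The numbers of genes with each pattern of calls were set against 10000 simulations of a model in which libraries differ in sensitivity alone.

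Genes are named by a rule fixed beforehand. It took up to 20 response-list members whose call differed, by covered bp at the time with the call, the 5 gained and the 5 lost genes with the most covered bp outside unnamed gene models, and the 5 broadest and 5 narrowest changes among response-list members called at both times. Genes outside this rule were picked after their values were seen, either to name the members behind a list's count or as examples, and are marked as such. The calling of gains and losses was run on simulated data with peaks added to or removed from 100 genes in each direction. All 100 gains and 100 losses were recovered, with 0 and 2 other genes called. Added peaks lay at the marked end and removal took all peaks within 5 kb, so recovery follows from the calling rule. It checks the code alone, and not peaks near the window edge, narrow peaks or a wrong marked end. Alternatives were reciprocal overlap of 50%, joining of peaks within 1 kb, call windows of 500 bp and 2.5 kb, breadth windows of 2.5 and 10 kb, and random lists without matching. Further alternatives, added after seeing the data, filtered peaks by width, took equal numbers of the widest peaks, or changed the part of the gene searched, the neighbours allowed, the meaning of an absent peak and the genes that random lists were drawn from. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.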

Results

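Promoter H3K4me3 was measured in granulosa cells from mice primed with eCG, before hCG (0 h) and 4 h and 12 h after it, with 1 library per time. The lists held 22236 peaks at 0 h, 23662 at 4 h and 20669 at 12 h on the chromosomes used, covering 8.87, 10.1 and 8.93 Mb. Median peak widths were 306, 315 and 333 bp, and the narrowest peaks had 136, 139 and 152 bp. A breadth ratio that starts or ends at such a width depends on that floor. Positions are in mm10, and covered bp means the length covered by peaks within 5 kb of a gene's marked end.

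The 3 libraries shared most of their peaks. Of the 0 h peaks, 82.0% (95% interval 81.5 to 82.5) were overlapped at 4 h and 75.2% (74.6 to 75.7) at 12 h. Shares of the 4 h peaks were 73.8% (73.2 to 74.3) at 0 h and 72.3% (71.7 to 72.8) at 12 h. Shares of the 12 h peaks were 78.5% (77.9 to 79.0) at 0 h and 84.4% (83.9 to 84.9) at 4 h. By covered bp the Jaccard index was 0.576 between 0 h and 4 h, 0.593 between 4 h and 12 h and 0.556 between 0 h and 12 h. Peaks within 1 kb of a gene end made up 68.0%, 64.8% and 67.3% of the lists at 0 h, 4 h and 12 h. Among peaks shared by all times these shares were 74.1%, 74.7% and 74.1%, and among peaks found at a single time they were 48.5% of 2840, 40.0% of 3928 and 43.8% of 2155. Peaks found at a single time were narrow, with median widths of 174, 175 and 195 bp.

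The comparison of 0 h with 4 h asks which promoters acquired the mark as the ovulatory signal took effect. Genes of the ovulatory response to LH stood out. Areg, an EGF-like ligand that acts in cumulus expansion, went from 0 covered bp at 0 h to 977 at 4 h, and Ptgs2, the inducible prostaglandin synthase, from 0 to 794. The matrix genes Tnfaip6 and Ptx3, which hold the expanded cumulus together, had 0 bp at 0 h and 1797 and 747 bp at 4 h. Star, which delivers cholesterol to the mitochondrion for steroid synthesis and was on the steroidogenesis and luteinization list instead, had 0 and 1567 bp.

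Of 40 ovulatory LH-response genes, 17 were called at 0 h and 28 at 4 h. The list gained 11 of its 23 uncalled members and lost 0, against a mean of 1.43 gains and a highest value of 7 in random lists. Besides Areg, Ptgs2, Tnfaip6 and Ptx3, the gained members included Timp1, a metalloproteinase inhibitor on chromosome X with 995 bp at 4 h, and the estrogen sulfotransferase Sult1e1 with 759 bp. Of 35 immediate early genes, 26 were called at 0 h and 33 at 4 h. They gained 8 of 9 uncalled members, more than the highest random value of 5, and lost the orphan receptor gene Nr4a3, whose covered bp was 543 at 0 h and 365 at 4 h. Among these gains Klf2 had 138 bp at 0 h and 1717 at 4 h, the neuronal activity gene Arc 0 and 1250, the AP-1 gene Fosl1 0 and 766, and the orphan receptor gene Nr4a1 0 and 704.

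Members called at both times were also broader at 4 h relative to other genes. The median centred log2 breadth ratio was 0.71 for the LH-response list, with 15 of 17 members broader and the value above those of all 10000 random lists (0.41 without peaks below the 25th width percentile), and 0.36 for immediate early genes, with 22 of 25 broader (percentile 99.96, but a ratio of 0.21 at percentile 95.1 with equal numbers of the widest peaks). The largest ratios were those of Runx2, a transcription factor gene induced in ovulatory follicles, at 3.92 (136 bp at 0 h and 2226 bp at 4 h), Junb at 3.64 (136 and 1839 bp), Cited4 at 3.05 (196 and 1756 bp) and the mRNA decay factor gene Zfp36 at 2.82 (137 and 1044 bp). The 0 h values of Runx2, Junb and Zfp36 were single peaks at or next to the narrowest width of that library (136 bp), so the size of their ratios depends on that floor. Sik1, a kinase gene induced by cyclic AMP, had a ratio of 1.82.

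Angiogenic and vascular signalling genes gained 5 of 19 uncalled members (percentile 99.7), and their median breadth ratio was 0.46 (percentile 99.85). The gained members Fgf2, Edn1, Ednrb, Sema3e and Dll4, named after their values were seen, had 142 to 362 bp at 4 h. The endothelial markers Kdr and Erg also gained a call, with 347 and 170 bp at 4 h, and Sox18 lost one, with 302 bp at 0 h, all 3 picked after their values were seen. Among cell cycle genes 3 of 8 uncalled members were gained, Ccne2 with 427 bp at 0 h and 758 at 4 h, and the inhibitor genes Cdkn2a and Cdkn2b, picked after their values were seen, with 139 and 247 bp at 4 h (percentile 99.4). Of 39 extracellular matrix proteases and inhibitors, 3 gained a call, Lox with 538 bp at 4 h, Mmp11 with 469 and Mmp15 with 185, the last 2 picked after their values were seen. In the same list 4 lost their call, Adamts17, Adam8, Adam12 and Loxl1, also picked afterwards and with at most 308 bp at 0 h (percentile 99.6, and 81.2 with narrow peaks left out). Cytokine and chemokine genes gained 4 of 29, including the colony-stimulating factor gene Csf1 with 699 bp at 4 h. Steroidogenesis and luteinization genes gained Star and Sfrp4 out of 14 (percentile 86.4), and their breadth percentile was 38.1. Cholesterol genes gained 0 of 6 and lost 0 of 26.

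The largest narrowing among response genes was at Grem1, a BMP antagonist gene of growing follicles, with 1585 bp at 0 h and 166 bp at 4 h (ratio -3.37). Hsd17b1, which encodes the estradiol-forming enzyme, had 3146 and 1304 bp (ratio -1.38), with another gene end within 2 kb. Nppc, the gene of the peptide that holds oocytes in meiotic arrest, had 1721 and 778 bp (ratio -1.26). Ccnb2 had 836 and 252 bp and the cholesterol synthesis gene Lss 468 and 139 bp. The 4 h value of Lss was a single peak of the narrowest width in that library. The follicular growth list as a whole had a median ratio of 0.03 (percentile 53.6), with 12 members broader and 12 narrower.

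In all, 10237 of 21887 protein-coding genes (46.8%, 46.1 to 47.4) were called at 0 h and 10607 (48.5%, 47.8 to 49.1) at 4 h. Between them 723 genes gained a call and 353 lost it, and the median log2 breadth ratio of the 9884 genes called at both times was 0.11. Some genes changed calls at the 1 kb window while peaks elsewhere within 5 kb were present at both times. Among them were Trib2 (2027 bp at 0 h and 2316 at 4 h), Actb (1124 and 1837 bp), Mcm2 (1034 and 1057 bp) and Mdc1 (1762 and 1465 bp). At Mcm2 and Mdc1 the peak at the marked end was gone at 4 h, and the covered bp came from peaks farther away. Of the 723 gained genes 560 had no peak within 5 kb at 0 h, and of the 353 lost genes 223 had none at 4 h. Among those, Hmga2 with 1319 bp and Cd24a with 1211 bp at 4 h were picked after their values were seen. The control list of housekeeping genes also gained 2 of 4 uncalled members, Actb and Tbp (the latter picked after its values were seen), at percentile 98.8 (46.8 with the 2.5 kb window), and the control list of unrelated lineages lost 3 of 4 called members at percentile 99.98 (94.7 with narrow peaks left out). At Actb, peaks inside the gene were present at 0 h, so its gain at the marked end need not be a gain at its promoter. With equal numbers of the widest peaks the cell cycle gain percentile was 96.1, and with narrow peaks left out the angiogenic and cell cycle gain percentiles were 96.6 and 94.5.

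**Figure D1:**
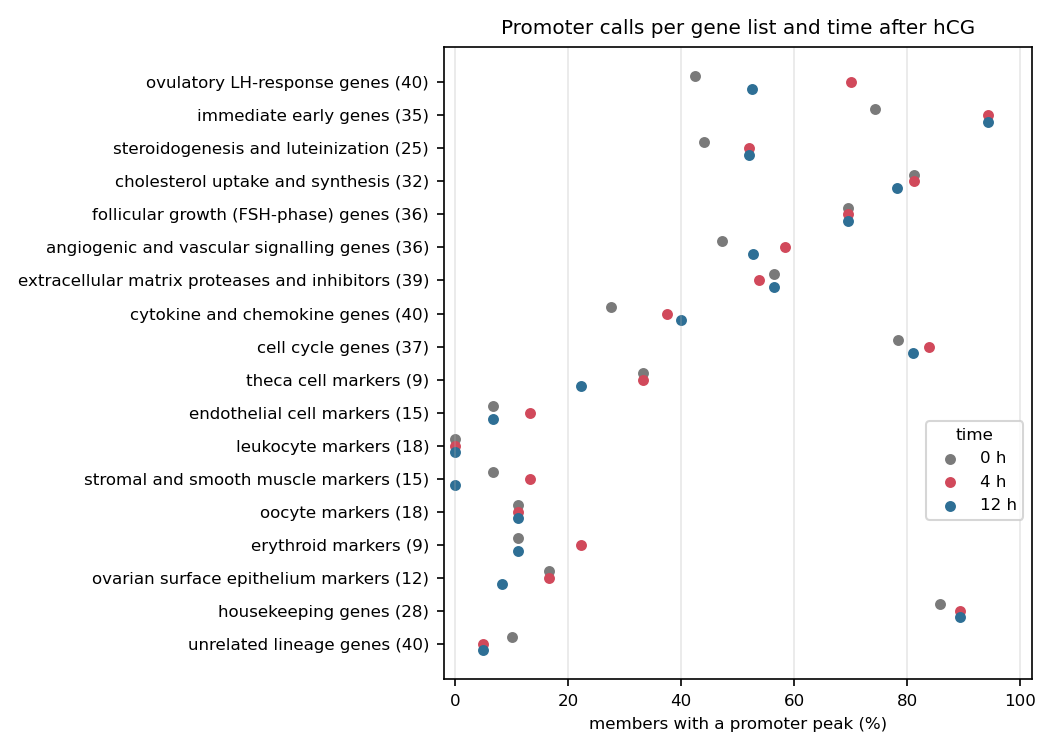
Share of the members of each fixed gene list (vertical axis, members found in brackets) with a promoter H3K4me3 peak (horizontal axis, percent) in the libraries at 0 h, 4 h and 12 h after hCG. A promoter peak is one within 1 kb of the marked gene end. Ovulatory LH-response genes were called in 17, 28 and 21 of 40 members and immediate early genes in 26, 33 and 33 of 35.

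**Figure D2:**
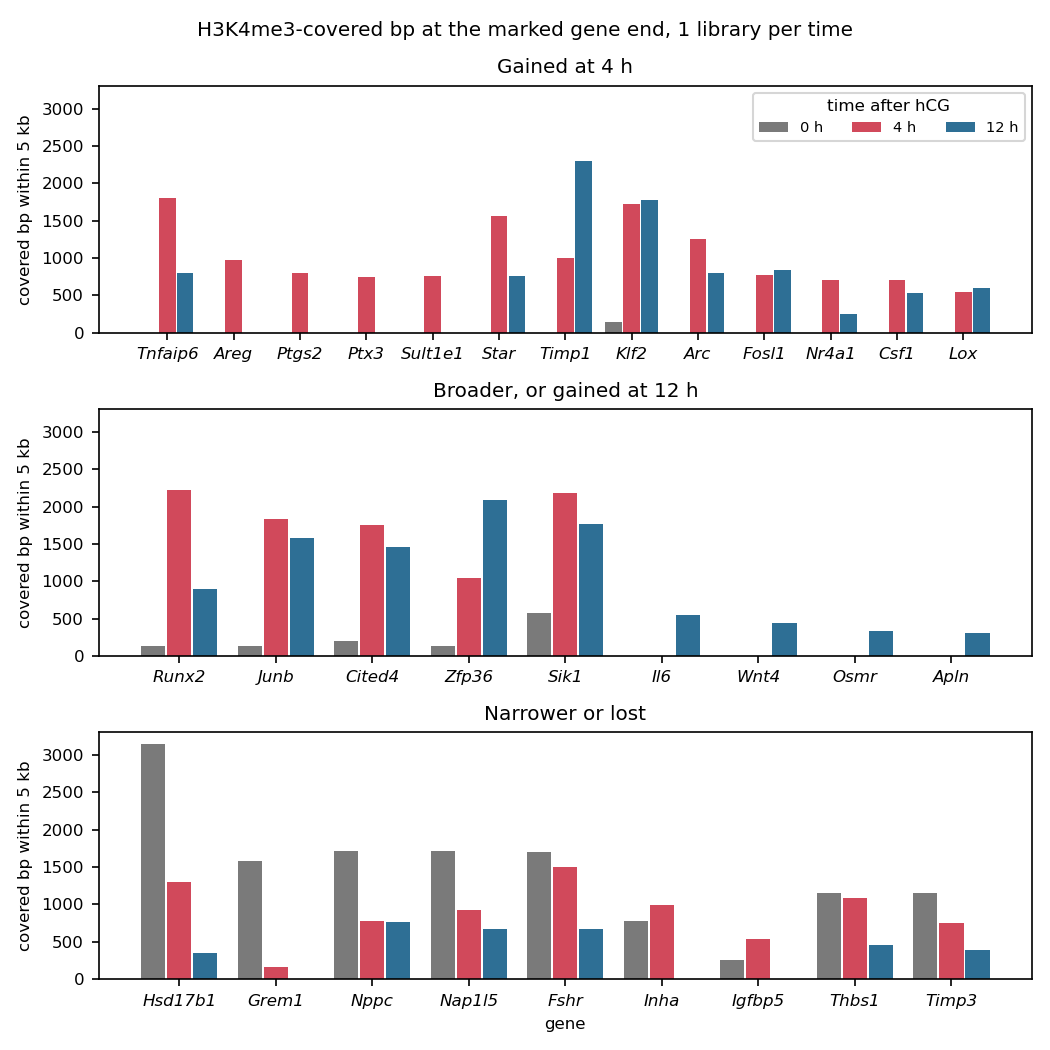
Length covered by H3K4me3 peaks within 5 kb of the marked gene end (vertical axis, bp) for genes of the response lists (horizontal axis) at 0 h, 4 h and 12 h after hCG, 1 library per bar. Areg, Ptgs2, Ptx3 and Sult1e1 had 0 bp at 0 h and 12 h, while Timp1 had 995 bp at 4 h and 2300 bp at 12 h.

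The comparison of 4 h with 12 h asks which of these marks lasted as luteinization went on. The peaks at Areg, Ptgs2, Ptx3 and Sult1e1 were gone at 12 h, with 0 covered bp each. Tnfaip6 had 1797 bp at 4 h and 794 at 12 h, Star 1567 and 757, and Timp1 995 and 2300, all 3 named here because of their gain at 4 h. Il6, the interleukin gene on this list, was called at 12 h alone, with 547 bp.

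The LH-response list lost 8 of its 28 called members, against a mean of 2.07 in random lists (percentile 99.96), and gained Il6. Of the 8 losses 6 were of calls gained at 4 h, and set against all genes gained at 4 h the list was unremarkable, with 5 of 11 gained calls kept and a mean of 5.33 in random draws (percentile 42.2). In the same interval the lists of other cell types together lost 7 of 13 called members, and all genes lost 7.40% of their calls. Besides the 4 genes above the losses were Vcan, a matrix proteoglycan gene with 2053 and 1293 bp, Cd34 with 419 and 220 bp, Prkg2 with 311 and 152 bp, and Cd44. Stromal and smooth muscle markers, 2 of 2 of which lost their call, had a loss percentile of 99.7 (50 with narrow peaks left out and 96.9 with equal numbers of the widest peaks). Immediate early genes lost 1 of 33, Egr4, and regained Nr4a3. The median centred breadth ratio of the LH-response list was -0.28 (percentile 0.61), and the one of immediate early genes was -0.05. In the immediate early list, Dusp6 had 1547 and 560 bp (ratio -1.34) and Nr4a1 704 and 255 bp (ratio -1.34). Cd44 and Egr4 were picked after their values were seen.

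Follicular growth genes had a median centred ratio of -0.36 over 22 members, with 13 narrower and 9 broader (percentile 0.03). With narrow peaks left out the median was -0.03 (percentile 43.6), and with joined peaks it was -0.26. Hsd17b1 had 1304 and 349 bp (ratio -1.77), and the calls at Inha, the inhibin alpha gene (995 and 0 bp, with another gene end within 2 kb), Igfbp5 (543 and 0 bp) and Grem1 (166 and 0 bp) were lost. The same list gained Inhbb (0 and 549 bp), Wnt4 (0 and 434 bp) and Igfbp4 (0 and 201 bp) among 11 uncalled members (percentile 99.8). Inhbb already had 681 bp at 0 h, outside the window used for calls. Angiogenic genes lost Fgf2, Edn1, Ednrb and Thbs1 (1080 and 450 bp), the last of which kept a peak just outside the 1 kb window. They gained Apln (0 and 301 bp) and Notch4 (595 and 953 bp, with another gene end within 2 kb). Cytokine genes gained the receptor genes Il6ra, Osmr and Tnfrsf11a, with 202, 336 and 152 bp, and lost Cxcl2 and Tnfsf11. Grem1, Igfbp4, Fgf2, Edn1, Ednrb, Il6ra, Tnfrsf11a and Cxcl2 were picked here after their values were seen, to name the members behind these counts. Members that were broader at 12 h included Lss (139 and 496 bp), the semaphorin receptor gene Nrp1 (246 and 753 bp), Abcb1b (295 and 844 bp) and adrenomedullin, Adm (167 and 456 bp).

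Across all genes 355 gained and 785 lost a call, of which 253 and 604 had no peak within 5 kb at the time without it. The median log2 breadth ratio was -0.13. Outside the lists, Fgd3, S100a6 and Rpp25 had 0 bp at 4 h and 1313, 1277 and 1227 bp at 12 h, and Rtkn2 had 1579 and 0 bp, all picked after their values were seen. The genes with the most covered bp among losses by rule, such as Zfp827 (1838 and 1279 bp) and Slc38a2 (1820 and 1219 bp), kept peaks within 5 kb. With peaks anywhere in the gene the LH-response list lost 5 members (percentile 93.0), and with narrow peaks left out its breadth percentile was 10.4.

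The comparison of 0 h with 12 h asks what differed across the whole interval. Timp1 (0 and 2300 bp), Klf2 (138 and 1776 bp), Fosl1 (0 and 834 bp), Egr3 (0 and 802 bp) and Arc (0 and 797 bp) had gained a call. Zfp36 (137 and 2090 bp, ratio 3.95), Junb (136 and 1579 bp, 3.55), Cited4 (196 and 1459 bp, 2.91) and Runx2 (136 and 895 bp, 2.73) were broader. The 0 h values of Zfp36, Junb and Runx2 lay at or next to the narrowest peak width. In the other direction Hsd17b1 went from 3146 to 349 bp (ratio -3.16), Grem1 from 1585 to 0 bp, and Fshr, the FSH receptor gene, from 1707 to 675 bp (ratio -1.32).

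Immediate early genes gained 7 of 9 uncalled members, above all random lists, and lost 0 of 26 (percentile 9.7). Their median breadth ratio was 0.50, also above all random lists. LH-response genes gained 6 of 23 (percentile 99.98), among them Tnfaip6, Timp1, Il6 and Abcb1b. They lost the calls at Vcan (1629 and 1293 bp) and Cd34 (251 and 220 bp), which kept peaks within 5 kb. Their median breadth ratio was 0.44 (percentile 99.88, but 89.4 with peaks within 1 kb joined, 90.9 with narrow peaks left out and 95.4 with equal numbers of the widest peaks). Angiogenic genes gained Apln, Sema3e, Dll4 and Notch4 of 19 (percentile 99.4), and cytokine genes gained 5 of 29, Csf1, Cxcl12, Osmr, Il6ra and Tnfrsf11a (percentile 99.3). Extracellular matrix genes gained Mmp11, Lox and Mmp15 and lost Mmp14, Adam8 and Adam12. The lost call at Mmp14 went with 422 bp at 0 h and 483 bp at 12 h, with another gene end within 2 kb. Its 12 h peaks lay outside the 1 kb window, so this was no loss of covered bp. Mmp11 had 0 bp at 0 h and 1147 bp at 12 h, with another gene end within 2 kb, and a single peak of 208 bp made up the part near its marked end. With the 2.5 kb window its change was -127 bp. Il6, Cd34, Apln, Sema3e, Dll4, Csf1, Cxcl12, Osmr, Il6ra, Tnfrsf11a, Mmp15, Mmp14, Adam8 and Adam12 were picked here after their values were seen, to name the members behind these counts.

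The follicular growth list had a median ratio of -0.29, with 14 of 23 members narrower (percentile 0.04). Besides Hsd17b1 and Fshr these included the imprinted gene Nap1l5 (1717 and 673 bp, ratio -1.34), and Inha and Grem1 lost their calls. These were 2 losses among 25 called members (percentile 67.2). The list also gained 2 of 11 uncalled members (percentile 94.6), so 25 were called at each time. The gain at Inhbb went with 681 bp at 0 h and 549 at 12 h. Timp3 (1147 and 394 bp) and Mmp16 (630 and 232 bp) were narrower among matrix genes. Cholesterol genes had a median ratio of 0.22 (percentile 97.8), with 19 of 25 members broader, and cell cycle genes one of -0.19 (percentile 2.33, and 3.01 among random lists without matching), with 21 of 28 narrower. Across all genes 572 gained and 632 lost a call, and the median log2 breadth ratio was -0.01. Apoa4 lost its call, going from 1684 to 0 bp.

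With peaks within 1 kb joined, the breadth percentiles were 6.50 for follicular growth genes, whose median was -0.12, and 83.1 for cholesterol genes, which were at 95.9 with narrow peaks left out and 97.3 with equal numbers. With narrow peaks left out the cytokine gain percentile was 95.7, without genes that have a neighbouring gene end the angiogenic one was 97.4, and the housekeeping list again gained Actb and Tbp, both picked after their values were seen (percentile 99.3, and 47.4 with the 2.5 kb window). The list of unrelated lineages lost 2 of 4 called members (percentile 98.9, but 91.7 with narrow peaks left out and 91.6 with equal numbers of the widest peaks).

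**Figure D3:**
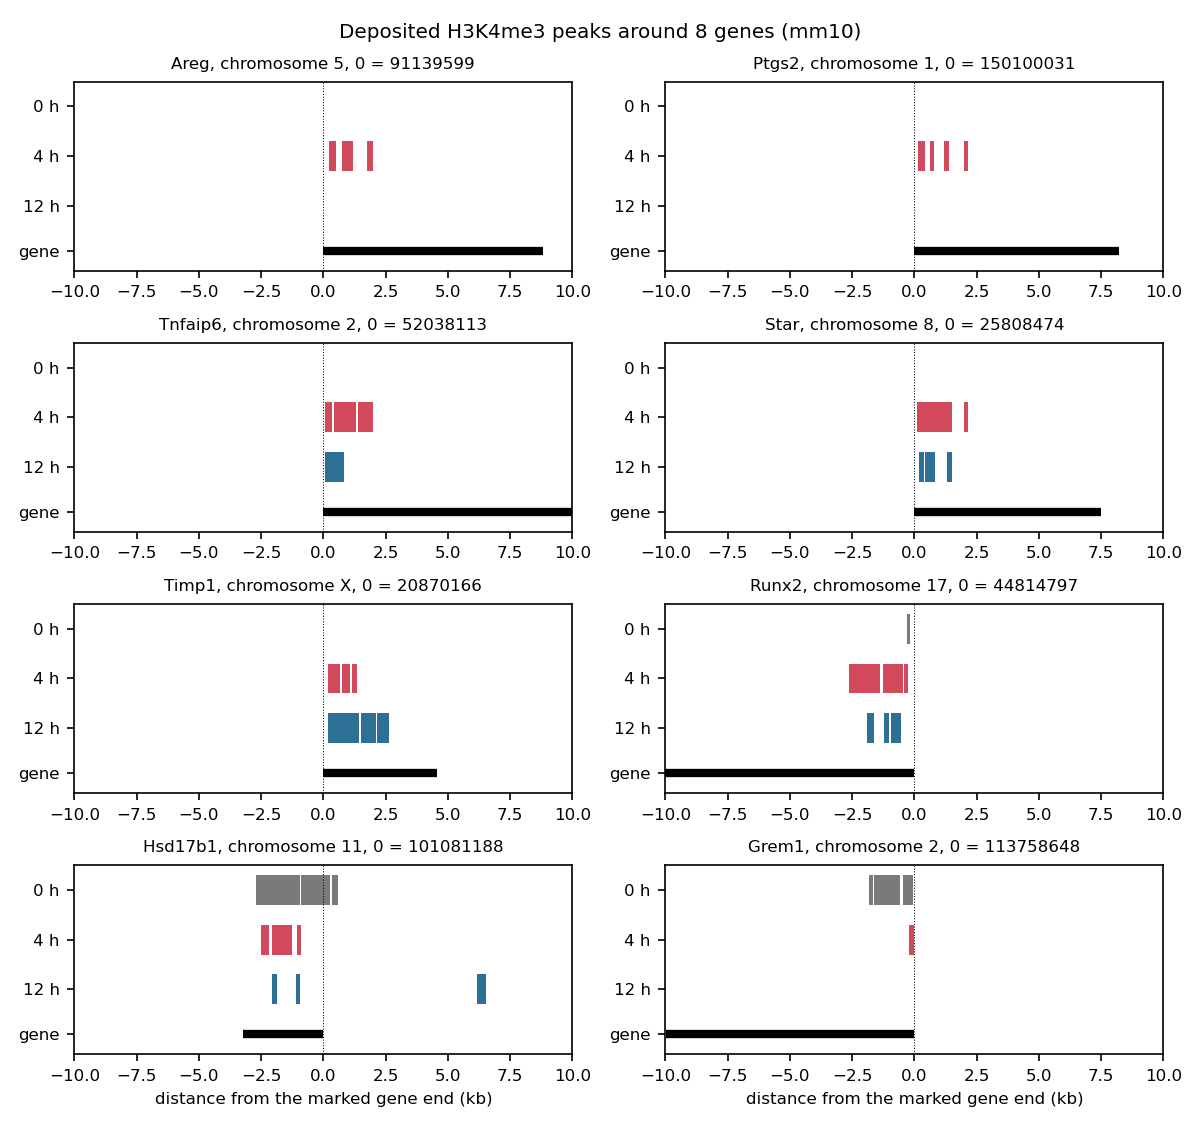
Deposited H3K4me3 peaks at 0 h, 4 h and 12 h (rows of blocks) within 10 kb of the marked gene end of 8 genes, with the annotated gene as a black bar (horizontal axis, distance in kb, mm10). Areg and Ptgs2 have peaks at 4 h alone, Timp1 at 4 h and 12 h, and the covered bp at Hsd17b1 were 3146, 1304 and 349.

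Over the 3 times, 9472 genes were called throughout and 10705 at no time. Calls at 4 h and 12 h but not 0 h were found for 350 genes, including Tnfaip6, Star, Timp1 and Klf2, and calls at 4 h alone for 373, including Areg, Ptgs2, Ptx3 and Sult1e1. A further 412 genes, including Grem1 and Inha, were called at 0 h and 4 h, 133 at 0 h and 12 h, 220 at 0 h alone and 222, including Il6 and Wnt4, at 12 h alone. If the libraries differed in sensitivity alone, 341 genes (simulated range 312 to 370) would be called at 4 h and 12 h without 0 h, and 414 (386 to 442) at 4 h alone.

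**Figure D4:**
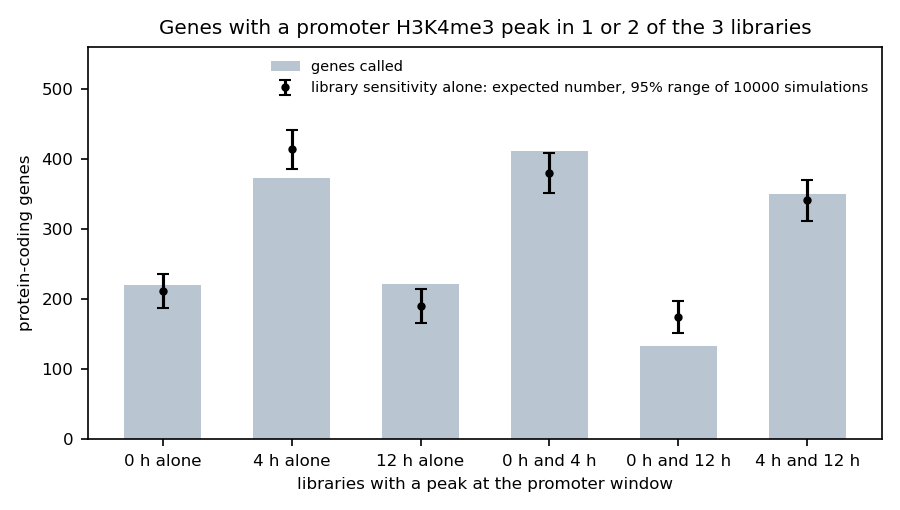
Protein-coding genes (vertical axis, number) called in 1 or 2 of the 3 libraries (bars, by pattern on the horizontal axis), with the expected number and 95% range of 10000 simulations in which libraries differ in sensitivity alone (points and lines). The bars for 4 h alone (373) and for 0 h and 12 h (133) lie below the range, and those for 12 h alone (222) and for 0 h and 4 h (412) above it. Within each of these pairs the departures mirror each other, since the model keeps each library's number of calls.

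Markers of other cell types were rarely called. Of 18 leukocyte markers 0 were called at each time, and endothelial markers were called in 1, 2 and 1 of 15 and stromal markers in 1, 2 and 0 of 15. From 0 h to 4 h the 7 lists together gained 6 of 86 uncalled members (6.98%, 2.60 to 14.6), which were Kdr, Erg, Myh11, Lhx8, Klf1 and Gpm6a, named to give the members behind the count after their values were seen, all with at most 462 bp at 4 h. In the same interval endothelial markers lost their 1 called member (Sox18, loss percentile 98.3, and 50 with narrow peaks left out). Theca markers were called in 3, 3 and 2 of 9, oocyte markers in 2 of 18 at each time, erythroid markers in 1, 2 and 1 of 9, and ovarian surface epithelium markers in 2, 2 and 1 of 12. Housekeeping genes were called in 24, 25 and 25 of 28 and genes of unrelated lineages in 4, 2 and 2 of 40.

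Several granulosa cell genes, picked after their values were seen, have peaks inside the gene and none at a gene end. Within the gene or 1 kb around it, Cyp19a1, the aromatase gene, had 2045, 845 and 382 covered bp at 0 h, 4 h and 12 h, and Cyp11a1, the side-chain cleavage enzyme gene, had 0, 437 and 353. Runx1 had 502, 1327 and 1440, the progesterone receptor gene Pgr 740, 845 and 414, and the endothelin gene Edn2 0, 0 and 240. Counted this way the LH-response list was called in 25, 37 and 34 of 40 members and follicular growth genes in 32, 30 and 30 of 36.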

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

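The tests of explanations here were all chosen after the results they address were seen.

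Peaks on the mitochondrial genome, which carries no histones and was used in no comparison, numbered 5 at 0 h, 3 at 4 h and 6 at 12 h, a signal in data outside the main measurement, and no explanation was tested.

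From 0 h to 4 h the ovulatory LH-response and immediate early lists together gained 19 of 32 uncalled members (59.4%, 40.6 to 76.3) and lost 1 of 43. With equal numbers of the widest peaks the gains stayed at percentile 100 of random lists, which argues against the number of peaks as the whole cause. Equal numbers do not equalise sensitivity, and the random lists were unmatched draws from all uncalled genes. A 4 h library more sensitive at genes active in these cells is therefore not excluded. The housekeeping control also gained calls at percentile 98.8 (46.8 with the 2.5 kb window). Markers of other cell types gained calls in 6.98% of uncalled members (upper limit 14.6), below the lower limit of these lists. That share pools 7 lists, of which the endothelial one alone gained 2 of 14, and cell types without a list were not covered. A change in the mix of cells is therefore not excluded. A further explanation is genes near the calling limit that change either way. The 19 gained members had a median of 713 covered bp at 4 h, against 321 for all 723 gained genes (percentile 99.9 of random draws). The 223 genes that lost all peaks within 5 kb had a median of 211 bp at 0 h. These values argue against this explanation for the set as a whole. They do not exclude it, since covered bp is not peak strength and the losses were measured in another library. For the 7 members at or below 613 bp, near the upper end of those losses, it stays open. A response of granulosa cells to hCG, which may account for the gains, stays open. So do a higher sensitivity of the 4 h library, a change in the mix of cells and a difference between animals or preparations, since each time has 1 library.

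Promoter calls differed between the 3 libraries. Of the 6 patterns of calls at 1 or 2 times, 4 lay outside the range simulated from a different sensitivity of each library alone, but a simulated range and single libraries exclude nothing. Nor are these separate departures, since the model keeps each library's number of calls and so mirrors them in pairs. The 12 h list differs from the others in that all 20675 of its peak names lack the tag nolambda, though the name of the list carries it, and its library ran in another lane. Whether its peak-calling setting differed is unknown. The other lane, or another setting if there was one, cannot be told apart from time for any difference that involves 12 h. A biological change by 12 h also stays open.

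Follicular growth genes had narrower promoter H3K4me3 at 12 h than at 0 h, with a median centred log2 ratio of -0.29. Among random lists matched on breadth the median lay at percentile 0.04 with the peaks as deposited, but at 6.50, with a median of -0.12, when peaks within 1 kb were joined. Neither a change that acts alike on domains of equal breadth nor peaks split differently in the 12 h library is therefore excluded. A decline of the follicular programme, the lane of the 12 h library and its peak-calling setting, if that differed, may each contribute and were not separated by any test.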

How the results depend on the processing

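Filters on peak width, equal numbers of the widest peaks, joining for peak counts, the part of the gene searched, the neighbours allowed, the stricter meaning of an absent peak and the genes that random lists were drawn from were chosen after seeing the data, and the other alternatives were planned. Of the values that answer a comparison, 203 recomputed under an alternative stayed within their limits, 50 moved and 1 reversed, and of the values of single genes and other lists 1877 stayed, 283 moved and 5 reversed. The cause of each change below was not tested unless the alternative's own construction gives it. Joining peaks within 1 kb left 12620, 13457 and 12380 peaks at 0 h, 4 h and 12 h by construction. Shares of overlapped peaks (0 h at 4 h, 0 h at 12 h, 4 h at 0 h, 4 h at 12 h, 12 h at 0 h and 12 h at 4 h) were 56.1%, 50.5%, 52.7%, 52.0%, 54.4% and 59.6% with 50% reciprocal overlap, by construction lower. They were 90.0%, 85.7%, 84.2%, 83.4%, 87.3% and 90.8% with joined peaks, 82.6%, 76.0%, 75.2%, 74.1%, 80.2% and 85.8% without peaks below the 25th width percentile, and 80.4%, 77.6%, 76.1%, 77.2%, 76.5% and 80.7% with equal numbers. Shares of peaks at a gene end at 0 h, 4 h and 12 h were 53.1%, 51.6% and 52.9% within 500 bp, 79.4%, 77.1% and 79.5% within 2.5 kb and 70.9%, 68.1% and 71.1% without the narrow peaks. Genes losing a call from 0 h to 4 h numbered 223 when no peak within 5 kb was allowed. Without narrow peaks the LH-response breadth ratio from 0 h to 4 h was 0.41, the angiogenic gain percentile 96.57, the follicular growth ratio from 4 h to 12 h -0.033 (percentile 43.6) and the cytokine gain percentile from 0 h to 12 h 95.74. With equal numbers of the widest peaks the immediate early breadth ratio from 0 h to 4 h was 0.21 (percentile 95.08), and the median log2 breadth ratio from 0 h to 12 h turned to 0.00527. With joined peaks the follicular growth ratio was -0.26 from 4 h to 12 h and -0.12 (percentile 6.495) from 0 h to 12 h. LH-response losses from 4 h to 12 h were 5 with peaks anywhere in the gene (percentile 93.05) and 5 when no peak within 5 kb was allowed. The change in covered bp from 4 h to 12 h turned to 10 at Mmp14 with equal numbers and to -84 at Thoc6 without narrow peaks. At Mmp11 the centred ratio from 4 h to 12 h turned to -0.45 with the 2.5 kb breadth window, and the change in covered bp from 0 h to 12 h turned to -127 with the 2.5 kb call window, which can move the marked end. At Inhbb the change from 0 h to 12 h turned to 41 without narrow peaks. Rankings of peaks by score, set out beforehand, were not run because the lists hold no score, and a choice of the 5'-most transcription start site was not run because the annotation used gives no strand. No paired analysis was possible because each time has 1 library and no label ties libraries to the same animals. Depth is unknown, so a missing peak does not show that the mark was absent.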

Other observations

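The test of the hypothesis here was chosen after the result was seen.

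Of the 723 genes that gained a call from 0 h to 4 h, 350 (48.4%) were still called at 12 h. Immediate early genes kept 7 of their 8 gained calls, Fosl1, Egr3, Nr4a1, Klf2, Dusp4, Ccn1 and Arc, and lost that of Egr4. LH-response genes kept 5 of 11, Tnfaip6, Timp1, Ptger4, Snap25 and Abcb1b (percentile 42.2 of random draws from the gained genes), and angiogenic genes kept Sema3e and Dll4 of 5. These genes are named to give the members behind the counts, after their values were seen. A hypothesis is that immediate early genes may keep gained promoter marks more often than other gained genes. Among random draws matched on covered bp at 4 h the number kept lay at percentile 94.2 (98.5 without matching). This decides nothing, since the 8 genes that gave the hypothesis are the ones tested, and the difference between the lists was not tested.

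Chromosome Y carried 28 peaks at 0 h, 43 at 4 h and 25 at 12 h in these female mice, and 0 of its 256 protein-coding genes were called at any time.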
